A study of Mus musculus with 4 samples.

How the data were processed

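Spatial transcriptomics was run on 4 sagittal mouse brain sections, 1 section for each of 4 groups: a control, a mouse resilient to chronic social defeat stress, a susceptible mouse, and a susceptible mouse given ketamine. Per the labels' protocols, frozen brain sections were placed on spatially barcoded slides, permeabilised and reverse transcribed on the slide, and the released cDNA was amplified by in vitro transcription and PCR. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the clustering method, and the method and reference data set that gave each spot its cell type shares are not given in the sources used here.

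The deposited tables hold 1 row per spot, with a cluster number and the fraction of the spot that the authors assigned to each of 67 cell types, plus a column for unknown. The fractions of every spot sum to 1 in the deposited tables. Of the 67 types, 47 are glutamatergic neurons, 11 are GABAergic neurons and 9 are non-neuronal, per the file headers. No deposited fraction above 0 was smaller than 10.1% of a spot, so smaller shares appear to have been set to 0 before deposit. The smallest kept share was 11.2% in the control, 10.1% in the resilient, 11.1% in the susceptible and 10.9% in the ketamine-treated section. A spot held at most 6 types. The mean number of types kept per spot was 2.25 in the control, 2.33 in the resilient, 2.10 in the susceptible and 2.17 in the ketamine-treated section. The share of spots holding a type can depend on this number. Unknown was always the whole of a spot, never a part of it. The cluster numbers ran from 1 to 17 and were taken as 1 clustering of all sections, since most numbers had similar leading cell types in each; no source used here states it. A further deposited table of t-SNE coordinates, which have no unit, listed 14809 barcodes, the total of the 4 sections. Only its barcodes were used. Every spot of the 4 sections was in it.

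Gene counts, total counts per spot and spot positions were not analysed here, so sequencing depth is unknown. The precision rests on the number of spots, which was 3733 in the control, 4156 in the resilient, 3443 in the susceptible and 3477 in the ketamine-treated section. A type seen in 0 spots had no kept share in any spot of its section. Were the spots an independent sample of more tissue, a limit of 3 spots would give its upper values there. These are 0.0804%, 0.0722%, 0.0871% and 0.0863% of spots, in that order. The limit does not cover shares too small to be kept, which could lie in any number of spots. The cell type shares are the authors' estimates, from a method not named in the sources used here, for spots that can hold several cells. They are not counts of cells. They are relative, so a higher share of one type lowers the others.

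The main measure was the mean deposited share of a type over all spots of a section, in percent. Types were also summed into classes: oligodendrocyte lineage (2 types, Oligo and OPC), astrocytes, microglia and macrophages (2 types, Micro and PVM), vascular cells (4 types, Endo, Peri, SMC and VLMC), glutamatergic neurons, GABAergic neurons and unknown. For each type, the share of spots holding any of it and the share of spots it led (the highest share in the spot) were given with exact Clopper-Pearson 95% intervals. With 1 section per group, spots are not replicates: the intervals cover counting error only, neighbouring spots are not independent, and no p-value was computed. Differences between mice, sections, slides and cutting planes are all within each comparison.

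Each difference was split by the deposited clusters into a part from unequal cluster proportions (the makeup part) and a part from unequal shares within clusters (the within part). A cluster with fewer than 20 spots in either section counted wholly in the makeup part. For a type concentrated in such a cluster, a large makeup part follows from this rule. Means with equal cluster weights used the 13 clusters with at least 20 spots in every section, weighted by their mean proportion. Clusters 5, 14, 16 and 17 were left out of these means. L2_3_IT_ENTl, L2_IT_ENTl, Meis2 and Pvalb were among the leading types of these clusters, so their equal-weight values cover only what lay elsewhere. The split was tested on simulated data drawn from the control section. Where the simulated difference came from lower shares within clusters only, a true within part of −7.04 percentage points was found as −7.33. Where it came from cluster proportions only, a true makeup part of −1.22 was found as −1.32, with a within part of 0.558 where the true value was 0. The association of types was described by Spearman correlation across the spots of each section, with Pearson correlation as the alternative.

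The rule for the types named in a comparison was fixed before the data were examined: Oligo and OPC always, and up to 10 types per direction with the largest ratio of mean shares, among types with a mean of at least 1% in 1 of the 2 sections. Alternatives were the median, a 10% trimmed mean, the share of spots led (for the lineage, spots whose leading type was Oligo or OPC), the share of spots with at least 0.1 of a type, equal cluster weights, clusters present in every section, spots not led by Oligo or OPC, and regions made by k-means (5 and 12 regions, 10 starts) from the shares of the other types. Leaving out the unknown spots, and counting spots by the class with the highest summed share, were added after seeing the data. An alternative was called moved when it left an interval around the main difference in which each mean was treated as a binomial share of spots. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.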

Results

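The study followed mice through chronic social defeat stress, a model in which repeated defeat by an aggressor leaves some mice socially avoidant (susceptible) and others not (resilient). Groups were set by a social interaction test, and some susceptible mice were given ketamine intraperitoneally at 10 mg/kg. The other mice received saline, and brains were taken 7 days after ketamine. The cell type shares below are estimates that the authors deposited, from a method not named in the sources used here. The series title places the question in myelin, the sheath that oligodendrocytes wrap around axons. Each of the 4 groups was represented by 1 sagittal section: control (3733 spots), resilient (4156 spots), susceptible (3443 spots) and ketamine-treated susceptible (3477 spots). There were no replicates, so every difference below is a difference between 2 sections and carries no test across mice.

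Glutamatergic neurons, astrocytes and oligodendrocytes made up most of every section. Glutamatergic types had a mean share of 39.6% in the control, 43.1% in the resilient, 45.6% in the susceptible and 46.1% in the ketamine-treated section. Astrocytes stood at 21.4%, 21.1%, 21.2% and 22.6% in the same order. The oligodendrocyte lineage had the widest range of the classes in percentage points, at 22.5% in the control, 16.4% in the resilient, 14.4% in the susceptible and 13.01% in the ketamine-treated section. GABAergic types ranged from 8.33% in the control to 11.4% in the resilient section. Vascular cells lay between 3.10% and 3.89%, and microglia and macrophages between 1.29% and 1.87%. Spots given no type were 3.64%, 2.31%, 4.27% and 3.54% of the sections.

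**Figure D1:**
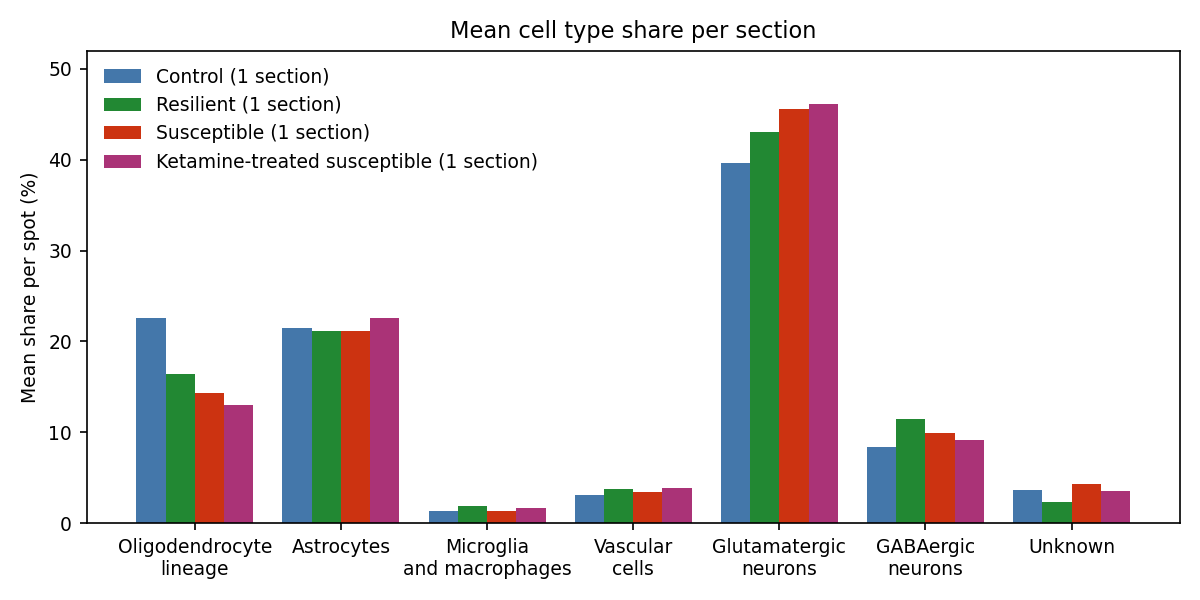
Mean share per spot (%, vertical axis) of 6 cell classes and of unknown in the control, resilient, susceptible and ketamine-treated section; each bar is 1 section, so there is no error bar. The oligodendrocyte lineage stood at 22.5% in the control and between 13.01% and 16.4% in the other sections, while astrocytes stayed between 21.1% and 22.6%.

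Oligo, the oligodendrocyte type listed beside OPC, accounted for nearly all of the kept lineage share. The headers do not say which stages of maturation it covers. Oligo was present in 42.2% of control spots (95% interval 40.7 to 43.8), 31.2% of resilient spots (29.8 to 32.6), 25.7% of susceptible spots (24.2 to 27.2) and 24.2% of ketamine-treated spots (22.7 to 25.6). It led 26.7% of control spots (25.2 to 28.1), 20.3% of resilient spots (19.1 to 21.6), 16.1% of susceptible spots (14.9 to 17.4) and 14.98% of ketamine-treated spots (13.8 to 16.2). The intervals of the susceptible and ketamine-treated sections overlapped in both measures, and those of the other sections did not overlap with each other or with these. Oligodendrocyte precursors (OPC), the dividing cells from which oligodendrocytes arise, were sparse among the kept shares, which miss any OPC share set to 0 before deposit. OPC was found in 29 control spots, 45 resilient spots, 43 susceptible spots and 32 ketamine-treated spots, with mean shares of 0.28%, 0.39%, 0.50% and 0.34%. As part of the kept lineage share, OPC made up 1.24%, 2.41%, 3.49% and 2.63% in the same order. The intervals of the OPC spot shares overlapped between all sections, from 0.52 to 1.11% in the control to 0.91 to 1.68% in the susceptible section.

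The susceptible section was compared with the control section to ask how the brain composition after stress with avoidance differed from that of a control. Oligo was lower, at 13.9% against 22.3%, a difference of −8.39 percentage points in which the control had 1.60 times the share. OPC was higher, at 0.50% against 0.28%, with overlapping spot intervals. Of the 21 types with a mean of at least 1% in either section, 12 were higher and 9 lower in the susceptible section, and 7 differed by at least 1.5-fold. The largest ratio was in L2_IT_ENTl, layer 2 neurons named for the lateral entorhinal cortex, at 1.19% against 0.126% (9.47-fold). CR (named for Cajal-Retzius cells, which are early-born neurons of the cortical surface) stood at 2.74% against 0.753% (3.64-fold), and Sst_Chodl, a long-range somatostatin neuron, at 2.28% against 0.952% (2.39-fold). At most 1.10% of the summed CR share of any section lay in clusters 2, 6 and 9, which cortical layer types or astrocytes led. Meis2 GABAergic neurons were at 2.46% against 1.33% (1.85-fold) and NP_SUB, near-projecting subicular neurons, at 1.41% against 0.872% (1.62-fold). Higher by less were L5_PT_RSP_ACA at 6.20% against 4.51%, VLMC at 1.42% against 1.13%, L4_5_IT_TPE_ENT at 4.16% against 3.54%, and L2_3_IT_ENTl and L2_3_IT_CTX at 1.14-fold and 1.13-fold.

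Besides Oligo, the deep-layer type L6b_CTX was lower in the susceptible section than in the control, at 0.668% against 1.10%. Parvalbumin interneurons (Pvalb), which are fast-spiking, were at 2.96% against 3.88%, with 8.05% of spots (7.16 to 9.004) against 10.9% (9.92 to 11.9). Layer 5 intratelencephalic neurons (L5_IT_CTX) were at 3.16% against 3.95%. CA1 pyramidal neurons were at 0.963% against 1.31%, a ratio of 0.733 that became 0.989 with equal cluster weights. Micro, L6_CT_CTX, L2_IT_RSP_ACA and Astro were between 0.92 and 0.99 of their control values. Of the L2_IT_ENTl difference, 0.776 of 1.06 points were the makeup part, as were −0.814 of the −0.926 points for Pvalb and 0.814 of the 1.32 points for Sst_Chodl. Cluster 17, which Pvalb led, had 45 control and 11 susceptible spots. L2_IT_ENTl was among the leading types of clusters 14 and 16. These had 67 and 81 susceptible spots against 4 and 0 control spots. Clusters 14, 16 and 17 counted wholly in the makeup part by rule. With equal cluster weights, the susceptible section had 0.980 times the control share of Pvalb, 1.22 times that of Sst_Chodl, 2.25 times that of CR and 1.11 times that of OPC. For L2_3_IT_ENTl, 94.0% of whose control share lay in the left-out cluster 5, the ratio over the remaining clusters was 2.09. With the same weights VLMC was lower, at 0.855 times, L2_IT_RSP_ACA slightly higher, at 1.03 times, and the control had 1.40 times the Oligo share. Oligo was lower in 12 of the 13 clusters that every section held with at least 20 spots, and the within part of its difference was −6.84 points against a makeup part of −1.55. The count of types differing by 1.5-fold became 12 when spots carrying each type were counted and 4 with equal cluster weights.

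The resilient section was compared with the control section to ask what accompanied stress without avoidance. Oligo was lower here too, at 16.0% against 22.3% (difference −6.25 points), and in 11 of the 13 shared clusters. OPC was at 0.39% against 0.28%. Of 23 types, 13 were higher and 10 lower, and 9 differed by at least 1.5-fold (14 when spots carrying each type were counted). L5_IT_TPE_ENT, layer 5 neurons named for temporal association, perirhinal, ectorhinal and entorhinal areas, had 5.96 times the control share, at 1.90% against 0.319%. Sst_Chodl stood at 4.38% against 0.952% (4.60-fold), in 7.94% of spots (7.14 to 8.80) against 2.06% (1.63 to 2.57). Cluster 4, where Sst_Chodl was among the leading types, had 426 resilient and 72 control spots, and 2.32 of the 3.42 points of the Sst_Chodl difference were the makeup part. With equal cluster weights the Sst_Chodl ratio was 1.71. CR was 2.85-fold higher (1.505-fold with equal weights), Ndnf_HPF 1.86-fold, L5_PT_RSP_ACA 1.72-fold and L4_5_IT_TPE_ENT 1.59-fold. NP_SUB, Micro, Endo and VLMC were higher by 1.47-fold, 1.38-fold, 1.35-fold and 1.29-fold, and with equal weights Micro was 1.55-fold higher and VLMC no longer higher (ratio 0.980).

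Meis2, L2_3_IT_ENTl and L2_IT_RSP_ACA had the lowest ratios of the resilient to the control share. Meis2 was at 0.354% against 1.33%, a ratio of 0.267 that became 0.424 with equal cluster weights, which leave out cluster 5. The makeup part was −0.611 of the −0.972 points, but cluster 5, with 2 resilient spots, counted in it wholly by rule. Meis2 averaged 6.22% over the 465 control spots of that cluster. L2_3_IT_ENTl was at 0.709% against 2.47%. L2_IT_RSP_ACA, layer 2 neurons named for retrosplenial and anterior cingulate cortex, stood at 2.10% against 4.38%, and L2_IT_RSPv at 4.03% against 5.60%, where the control had 1.39 times the resilient share, or 1.64 times with equal weights. The ratios of CA1, L2_3_IT_CTX, L5_IT_CTX and Pvalb were 0.69, 0.75, 0.84 and 0.88, and that of Astro was 0.99; for Pvalb it became 1.03 with equal weights. The sections did not hold the clusters in the same proportions: cluster 5, which held 94.0% of the summed L2_3_IT_ENTl share in the control, had 465 control spots and 2 resilient spots. With equal weights for the clusters present in all sections, L2_3_IT_ENTl was no longer lower in the resilient section, at 0.300% against 0.161%.

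Susceptible and resilient sections were compared directly, since both came from defeated mice that differed in behaviour. Oligo was at 13.9% in the susceptible and 16.0% in the resilient section (difference −2.14 points), and the intervals of its spot shares did not overlap. The lineage difference of −2.03 points became −0.932 over the clusters present in every section and −1.40 with equal cluster weights, with a counting interval of −3.17 to 0.363 that includes 0. Within clusters the direction was mixed, with lower values in the susceptible section in 7 of 13 shared clusters and higher values in 6. OPC was at 0.50% against 0.39%. Of 23 types, 9 were higher and 14 lower in the susceptible section, and 10 differed by at least 1.5-fold (6 with equal cluster weights). Meis2 was 6.95-fold higher, in 6.19% of spots (5.40 to 7.04) against 1.13% (0.832 to 1.501). L2_3_IT_ENTl was 3.99-fold higher, L2_IT_RSP_ACA 1.99-fold, L2_IT_ENTl 1.95-fold, L2_IT_RSPv 1.54-fold and L2_3_IT_CTX 1.51-fold. With equal weights, which leave out cluster 5, L2_3_IT_ENTl was 1.12-fold and L2_3_IT_CTX 1.44-fold higher, and the OPC ratio was 0.988. The makeup part of L2_3_IT_ENTl was 2.22 points, against a whole difference of 2.12, but cluster 5, with 2 resilient spots, counted in it wholly by rule. At most 13.1% of the summed L2_IT_RSPv share of any section lay in clusters 2, 6 and 9, which other cortical layer types or astrocytes led. CR, NP_SUB and Astro were 1.28, 1.10 and 1.00 times the resilient share.

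Ndnf_HPF had the lowest ratio of the susceptible to the resilient share, at 0.771% against 1.76%. Also lower were L5_IT_TPE_ENT at 0.974% against 1.90%, Sst_Chodl at 2.28% against 4.38% and L6b_CTX at 0.668% against 1.19%. With equal weights the ratios were 0.683 for Ndnf_HPF and 0.712 for Sst_Chodl. Microglia (Micro), the resident immune cells of the brain, were at 0.97% against 1.45%, in 2.93% of spots (2.40 to 3.55) against 4.38% (3.78 to 5.05). Susceptible spots also kept fewer types on average, 2.10 against 2.33, which can lower the share of spots holding a type. Endo, L4_5_IT_TPE_ENT, L6_CT_CTX, L5_PT_RSP_ACA and Pvalb had 0.68, 0.74, 0.80, 0.80 and 0.86 of the resilient share.

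**Figure D2:**
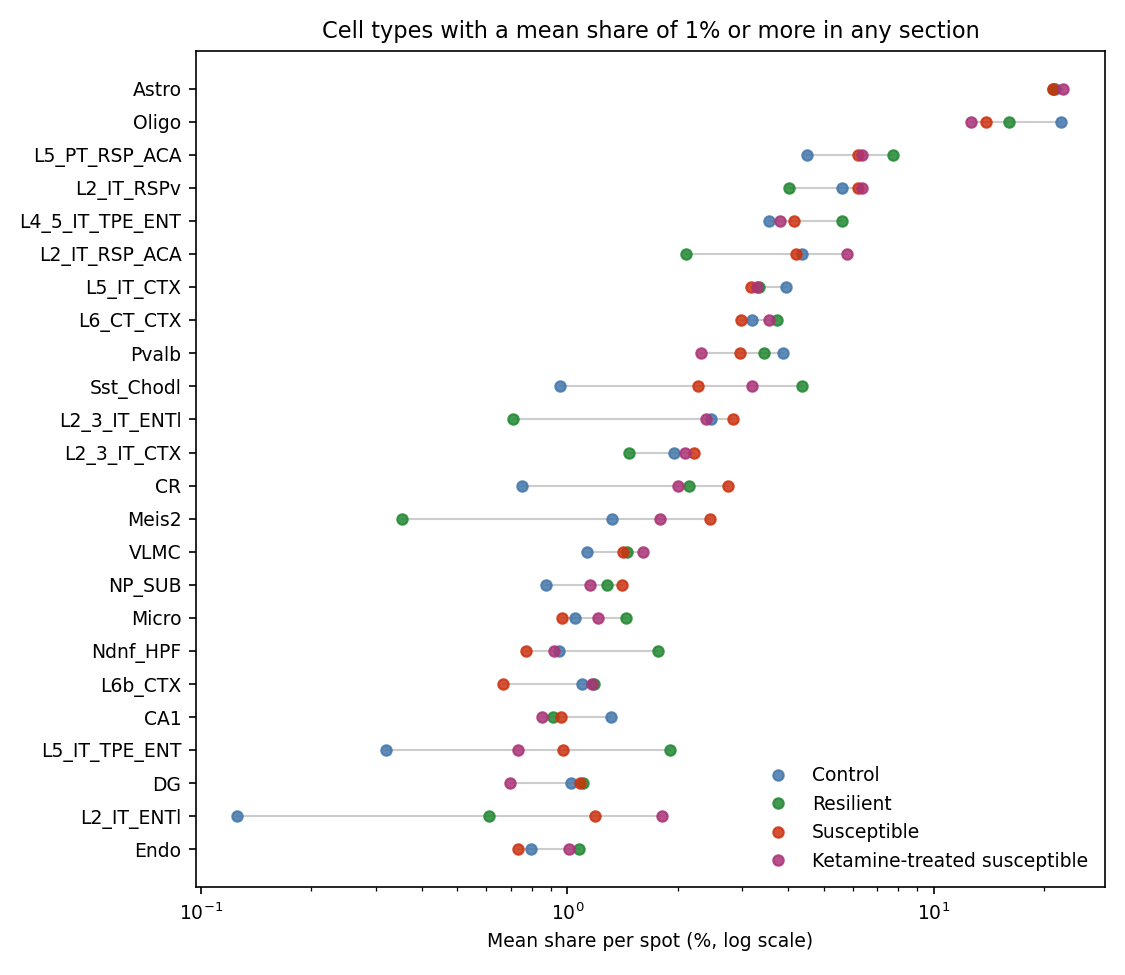
Mean share per spot (%, log axis) of each cell type that reached 1% in any section; points are the 4 sections by colour, and grey lines join the lowest and highest. By ratio, Astro varied least, from 21.1% to 22.6%, and L2_IT_ENTl varied most, from 0.126% in the control to 1.81% in the ketamine-treated section.

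The ketamine-treated section was compared with the susceptible section to ask what differed 7 days after the drug. By mean share, 3 of 21 types differed by at least 1.5-fold, against 6 to 10 in the other comparisons; the 3 became 5 by spots led and 6 by spots carrying each type. Oligo was at 12.7% in the ketamine-treated and 13.9% in the susceptible section, a difference of −1.21 points with overlapping spot intervals. OPC was at 0.34% against 0.50%, also with overlapping intervals. The lineage as a whole was lower by 1.37 points, and Oligo was higher in 7 and lower in 6 of the 13 shared clusters, with a median cluster difference of 0.009 points. Of the clusters left out of this count, Oligo was higher in the ketamine-treated section in cluster 5 (4.16% against 0.629%) and cluster 16 (9.24% against 5.41%). It was lower in cluster 14 (3.42% against 5.16%). In cluster 5, Oligo was in 6.83% of ketamine-treated spots (4.22 to 10.3) against 0.837% of susceptible spots (0.102 to 2.99). Over the whole section, the oligodendrocyte share after ketamine was not above that of the susceptible section.

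Of the 21 types, Oligo included, 12 were higher and 9 lower in the ketamine-treated section. L6b_CTX was at 1.17% against 0.668% (1.75-fold), in 2.44% of spots (1.957 to 3.01) against 1.34% (0.98 to 1.78). The control section was at 1.10%. L2_IT_ENTl was at 1.81% against 1.19% (1.52-fold), Sst_Chodl at 3.18% against 2.28% (1.40-fold) and L2_IT_RSP_ACA at 5.80% against 4.196% (1.38-fold). Endo, Micro, L6_CT_CTX, VLMC, Astro and L5_IT_CTX were higher by 1.37-fold, 1.26-fold, 1.19-fold, 1.13-fold, 1.07-fold and 1.04-fold. Dentate gyrus granule neurons (DG) were lower, at 0.696% against 1.08%, with overlapping spot intervals of 0.654 to 1.33% and 1.08 to 1.91%. Meis2 was at 1.79% against 2.46%, CR at 2.01% against 2.74% and Pvalb at 2.32% against 2.96%. NP_SUB, L2_3_IT_ENTl, L4_5_IT_TPE_ENT and L2_3_IT_CTX had 0.82, 0.84, 0.92 and 0.95 of the susceptible share. With equal cluster weights the ratios were 1.14 for L2_IT_ENTl, 0.951 for L5_IT_CTX, 0.745 for DG, 0.548 for Meis2 and 0.556 for L2_3_IT_ENTl. Those of L2_IT_ENTl and L2_3_IT_ENTl leave out clusters 5, 14 and 16, where these types were among the leading ones. That of Meis2 leaves out cluster 5, where Meis2 was also among the leading types. In that cluster it averaged 9.10% in the ketamine-treated and 8.09% in the susceptible section.

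Set against the control, the ketamine-treated section had the largest difference in mean oligodendrocyte share of the 5 comparisons. Oligo was at 12.7% against 22.3%, a difference of −9.60 points, and was lower in 12 of 13 shared clusters. OPC was at 0.34% against 0.28%. Pvalb was the next lowest by ratio, at 2.32% against 3.88%, in 6.67% of spots (5.87 to 7.55) against 10.9% (9.92 to 11.9). CA1, DG, L5_IT_CTX and L2_3_IT_ENTl had 0.65, 0.68, 0.83 and 0.97 of the control share. Of 22 types, 16 were higher and 6 lower, and 6 differed by at least 1.5-fold (3 with equal cluster weights). L2_IT_ENTl was 14.4-fold higher, with 106 spots against 12, Sst_Chodl 3.35-fold and CR 2.67-fold. VLMC, L5_PT_RSP_ACA, Meis2, L2_IT_RSP_ACA, NP_SUB, Endo and Micro were between 1.15-fold and 1.42-fold higher. Cluster 14, which L2_IT_ENTl led, had 95 spots in the ketamine-treated and 4 in the control section. Most of that type's difference was a makeup part, 1.33 of 1.68 points, in which cluster 14 counted wholly by rule. With equal cluster weights the ratios were 8.15 for L2_IT_ENTl, 1.52 for Sst_Chodl, 1.78 for CR, 1.16 for L2_3_IT_ENTl, 0.866 for VLMC, 0.846 for OPC, 0.845 for CA1 and 0.815 for Pvalb. The values for L2_IT_ENTl and L2_3_IT_ENTl leave out clusters 5, 14 and 16, where these types were among the leading ones. Of the −1.57 points for Pvalb, −1.06 were the makeup part.

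The share of oligodendrocytes differed between sections by region. Cluster 7, where Oligo made up most of the share, took 6.67% of control spots (5.89 to 7.52), 5.56% of resilient spots (4.88 to 6.30), 7.00% of susceptible spots (6.17 to 7.90) and 6.87% of ketamine-treated spots (6.05 to 7.77). Inside it the mean Oligo share was 70.1%, 71.6%, 72.1% and 70.4%. Outside cluster 7, Oligo averaged 18.8% in the control, 12.8% in the resilient, 9.50% in the susceptible and 8.41% in the ketamine-treated section. Cluster 1, led by Oligo and Astro, was the largest in the control, and Oligo was present in 66.3% of its control spots (63.2 to 69.3), 66.8% of resilient (63.6 to 69.9), 53.9% of susceptible (49.8 to 57.9) and 46.5% of ketamine-treated spots (42.1 to 51.0). In cluster 3, led by Astro, the control stood apart, with Oligo in 62.1% of spots (56.6 to 67.4) against 32.5%, 33.8% and 36.7% in the resilient, susceptible and ketamine-treated sections. Cluster 8, also led by Astro, had 31.0% Oligo in the control and 8.88%, 8.23% and 12.03% in the others, from 83 control spots. In cluster 5, where the resilient section had 2 spots, Oligo was in 23.7% of 465 control spots (19.9 to 27.8). There it was in 0.837% of susceptible (0.102 to 2.99) and 6.83% of ketamine-treated spots (4.22 to 10.3). In cluster 6 (led by L2_IT_RSP_ACA), cluster 9 (led by Astro and cortical layer types) and cluster 10 (led by Astro, DG and CA1), Oligo averaged at most 2.88% in any section.

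**Figure D3:**
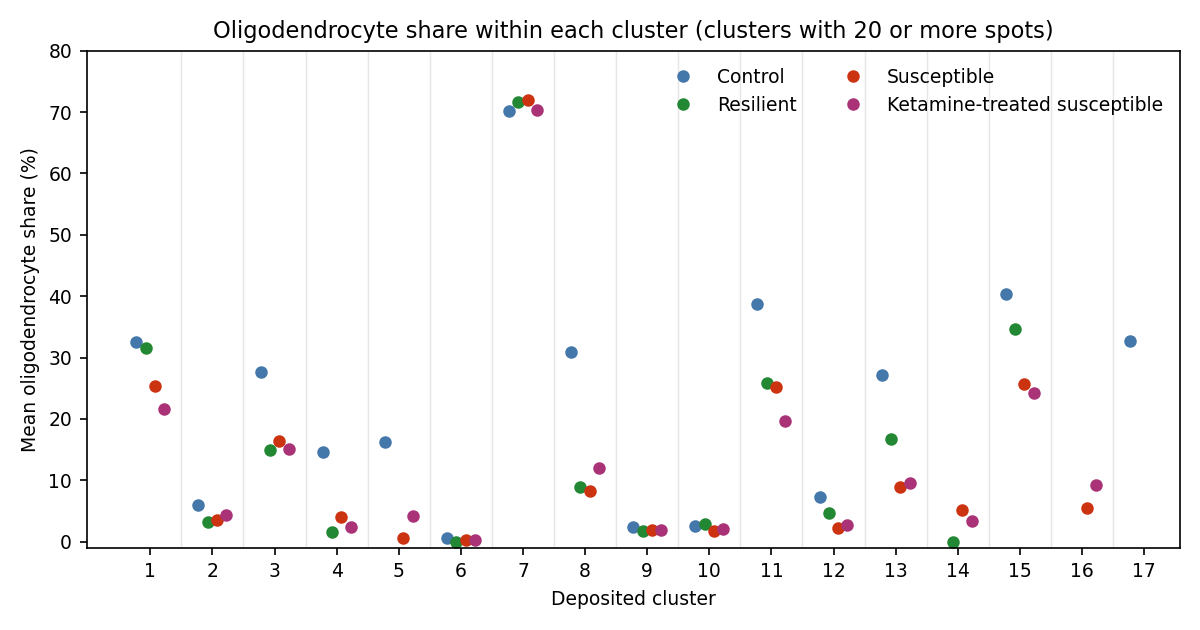
Mean Oligo share (%, vertical axis) in each deposited cluster (horizontal axis) for the 4 sections, shown where a section had 20 or more spots in the cluster. The sections lie between 70.1% and 72.1% in cluster 7, while in cluster 8 the control is at 31.0% and the others at 8.23% to 12.03%.

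With equal weights for the 13 clusters that every section held, the lineage stood at 22.3% in the control, 17.4% in the resilient, 16.0% in the susceptible and 14.9% in the ketamine-treated section. The order of the sections was the same as without weights. The differences from the control became −4.88 points for the resilient, −6.29 for the susceptible and −7.39 for the ketamine-treated section, and that between ketamine-treated and susceptible became −1.11. The clusters were presumably built from the same RNA as the shares, so they are not an independent map of anatomy.

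Across spots, the oligodendrocyte lineage was inversely related to glutamatergic neurons in each section, with Spearman coefficients of −0.50 in the control, −0.42 in the resilient, −0.40 in the susceptible and −0.39 in the ketamine-treated section. Spearman coefficients with astrocytes were between −0.09 and −0.06, and Pearson coefficients between −0.18 and −0.15. For microglia and macrophages the Spearman coefficients were 0.03 to 0.07 and the Pearson coefficients −0.01 to 0.02. L2_IT_RSPv had Spearman coefficients of 0.05 to 0.14 and Pearson coefficients of −0.05 to 0.03. For microglia and macrophages and for L2_IT_RSPv, the 2 measures had opposite signs in the control, susceptible and ketamine-treated sections, while both were above 0 in the resilient section. Shares within a spot sum to 1, which pushes such coefficients below 0, and spots are not independent replicates.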

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

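No paired analysis was possible because each group had 1 section, and for the same reason no replicate could be left out. Leaving out the unknown spots and counting spots by their leading class were chosen after seeing the data. Oligodendrocyte lineage differences kept their sign under all alternatives except the median, which was 0 in every section because fewer spots held the lineage than lacked it. Medians of single types were not run. As a share of spots carrying the lineage, the differences were −16.1 points (susceptible against control), −10.9 (resilient against control), −5.25 (susceptible against resilient) and −17.8 (ketamine-treated against control). As a share of spots whose leading type was Oligo or OPC they were −10.3 for susceptible against control, −4.19 for susceptible against resilient and −11.7 for ketamine-treated against control; by leading class they were −9.78, −3.33 and −11.1. Without the spots led by Oligo or OPC, which by construction removes most of it, the 4 differences shrank to −3.23, −2.86, −0.364 and −3.51, in the order given for spots carrying it. Equal cluster weights gave −6.29 for susceptible and −7.39 for ketamine-treated against control, and weighting by 5 k-means regions in place of the deposited clusters gave −9.61 for the latter. The causes of these shifts were not tested. The difference between ketamine-treated and susceptible ranged from −1.70 (spots carrying the lineage) to −0.280 (spots not led by Oligo or OPC), apart from the median. Among spots led by a type with at least 0.5 of the share, Oligo led 28.9% in the control. The number of types differing by 1.5-fold became 12 (spots carrying the type) or 4 (equal cluster weights) for susceptible against control, and 14 (spots carrying) for resilient against control. It became 6 (equal weights) for susceptible against resilient, 5 (spots led) or 6 (spots carrying) for ketamine-treated against susceptible, and 3 (equal weights) for ketamine-treated against control. Of the other values (single classes, types and associations), 784 stayed within their interval, 141 moved and 10 reversed, not counting 3 settings that could change nothing. A value was called reversed only if its sign changed and the interval of the main value excluded 0. Other changes of sign, such as those of VLMC against the control with equal cluster weights, were counted as within the interval or moved. The 10 are therefore not all the changes of direction. Resilient against control, L2_3_IT_ENTl became 0.140 points higher with equal weights and 0.141 higher over clusters present in every section, and unknown became 1.17 points higher over the latter. GABAergic neurons, susceptible against resilient, became 0.0151 points higher with equal weights. With Pearson in place of Spearman correlation, the association of the lineage with L2_IT_RSPv became −0.0335 in the control, −0.0239 in the susceptible and −0.0480 in the ketamine-treated section, and that with microglia and macrophages −0.00493, −0.00692 and −0.0104 in the same sections. The L2_3_IT_ENTl and unknown reversals follow from leaving out cluster 5, and the cause of the others was not tested. Dividing shares by their sum, setting shares under 0.05 to 0, and keeping only spots of the coordinate table changed nothing, by construction of the files, and say nothing about stability. Depth could not be assessed.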

Other observations

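Microglia in cluster 7 and perivascular macrophages in cluster 12, which the comparisons did not single out, were chosen after their values were seen. In the oligodendrocyte-rich cluster 7, microglia (Micro) were present in 18.2% of resilient spots (95% interval 13.4 to 23.8), against 8.03% of control (4.98 to 12.1), 8.30% of susceptible (5.14 to 12.5) and 8.37% of ketamine-treated spots (5.19 to 12.6). In cluster 12, led by VLMC, the fibroblast-like cells of the brain's coverings, PVM (perivascular macrophages) were in 31.0% of ketamine-treated spots (21.5 to 41.9) and 30.3% of resilient spots (21.0 to 41.0). The values were 18.3% in the susceptible (10.1 to 29.3) and 15% in the control section (7.10 to 26.6), with overlapping intervals. VLMC itself was in 83.9% to 88.8% of the spots of that cluster in every section.

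The hippocampal types DG and CA1 lay mostly in the same cluster. Cluster 10 held 93.5% to 96.9% of the summed DG share and 71.9% to 86.9% of the CA1 share of each section. In that cluster astrocytes averaged 39.4% in the ketamine-treated section, against 28.0% in the control, 28.3% in the resilient and 30.1% in the susceptible section. The shares of cluster 10 spots holding astrocytes overlapped, from 65.0% (55.9 to 73.4) in the ketamine-treated to 51.7% (43.3 to 60.0) in the susceptible section.

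The tests below were chosen after the values they bear on were seen, except those with equal cluster weights and with 12 k-means regions, which were planned. For equal cluster weights the criterion was written after the value was seen, and for the k-means regions before. For the even spread of RNA and for an equal added share, the criterion was also revised after its value was seen. No biological explanation can be separated from the section in a design with 1 section per group, so an effect of stress or treatment stays open and untested for each pattern.

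The control section had more oligodendrocyte share than the other 3 sections. Different proportions of the deposited clusters are not the whole reason: with equal cluster weights the smallest difference from control was −4.88 points (counting interval −6.77 to −3.02). Different structures cut within the same cluster may still contribute, since no spot positions were used, and regions made from the other types left a smallest difference of −5.21 points. Oligodendrocyte RNA spread evenly over the control section also stays open. In clusters 6, 9 and 10 together the control exceeded another section by at most 0.574 points (−1.17 to 2.27), but an evenly added share below about 10% of a spot may have been set to 0 before deposit. The test of an equal added share did not decide it either. At 2 times the smallest share kept, the control had 40.7% of spots, at least 9.01 points (6.87 to 11.1) more than held any of the lineage in another section. At 4 times it had 23.6%, which is not above the 24.8% to 31.7% that held any in the other sections. The deposited fractions sum to 1 although small ones are missing, so the kept ones appear to have been rescaled, by an unknown factor, and the total RNA of each spot is unknown.

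L2_IT_RSPv, named for layer 2 of ventral retrosplenial cortex, made up 4.03% to 6.36% of every section, yet at most 13.1% of its summed share lay in clusters 2, 6 and 9, which other cortical layer types or astrocytes lead. Those clusters held 95.4% to 98.9% of L5_IT_CTX, 85.8% to 99.7% of L2_3_IT_CTX, 77.5% to 85.7% of L2_IT_RSP_ACA and 61.2% to 76.4% of L5_PT_RSP_ACA, which is partly built in, since such types being among their leaders is why the clusters were picked. Clusters 1, 4 and 11, which are rich in oligodendrocytes or astrocytes, held 75.3% to 81.2% of L2_IT_RSPv, 75.5% to 91.4% of Sst_Chodl, 58.1% to 80.6% of CR and 11.6% to 23.3% of L5_PT_RSP_ACA. The high values are partly built in here too. L2_IT_RSPv was among the leading types of each of these clusters, and Sst_Chodl and CR were among those of cluster 4. CR had 0.502% to 1.10% of its summed share in clusters 2, 6 and 9. A candidate explanation for L2_IT_RSPv is that it stands in for neurons the list of types lacks: all neuronal names in the headers refer to cortical and hippocampal types or to interneuron markers, while the sections are sagittal brain sections that may hold other neurons. If so, differences in such types between sections would not be differences in the named neurons.

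The resilient section held 2 spots of cluster 5. Its lower L2_3_IT_ENTl share against the control came with that gap, since outside cluster 5 the resilient share was higher, at 0.710% against 0.170%. The makeup part of 107% of the difference is no test of this, because cluster 5 counted in it wholly by rule. The gap does not account for the lower Meis2 share against the susceptible section: the makeup part was 18.1% of the difference, and outside cluster 5 Meis2 stood at 0.354% against 2.04%. In cluster 8, Meis2 averaged 1.23% in the resilient, 2.81% in the control, 6.47% in the susceptible and 6.67% in the ketamine-treated section. In cluster 13 it averaged 10.4% in both the control and the susceptible section and 2.53% in 32 resilient spots. With equal cluster weights, which leave out cluster 5, the susceptible section stood at 2.08% and the control at 0.810%. The susceptible share was thus also high against the control. Why Meis2 differed between the sections was not tested.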
